A study of Homo sapiens with 6 samples.

How the data were processed

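Total RNA of MCF7 cells was measured on 6 Affymetrix whole-transcript arrays, 3 of untreated cells and 3 of cells given 10 ng/ml of TGF-β1 for 4 days with a renewal every 2 days. The values are deposited log2 signals, 1 per probe set (transcript cluster) and array, as the authors made them. The submitters' processing notes name Affymetrix Expression Console without a version, and the methods of background correction, summarisation and normalization are not stated. The array medians ranged from 5.42 to 5.51 and all values from 2.20 to 14.4, which is a log2 range, so no transformation or pseudocount was applied. No pair among the 15 pairs of arrays shared more than 0.0276% identical values, so no array was a copy of another. Background levels and single probes were not used here, so no probe set was called absent, and the number of arrays limits the precision.

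Probe sets were named from the platform annotation supplied with the values, updated through a RefSeq gene table of the human reference assembly. Of 65199 probe sets, 22631 had 1 gene symbol, 1384 had several and 41184 were not listed. Of those with 1 symbol, 20439 were matched through the gene identifier, 1896 through a current symbol and 292 through a synonym, and 4 kept the symbol of the annotation. The 22631 probe sets stand for 22271 distinct genes. Probe sets with several genes are not named, and a probe set that is not listed is unnamed here, not without a gene. Gene types came from the same table, which gave 1974 lncRNA and 17298 protein-coding probe sets. A gene with several probe sets is represented by the one with the highest mean over the 6 arrays. No coordinates are given, since no genome sequence was used. XIST and Y-linked genes were left out of all named genes.

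Groups and replicate numbers came from the sample titles. Treated arrays were compared with untreated arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings, residual df 4, prior df 1.96, two-sided moderated test), with Benjamini-Hochberg adjustment over all 65199 probe sets, and an adjusted p under 0.05 was called. Counts at a 2-fold change used the same fit and an absolute log2 change of at least 1. No filter was applied. The fit without a replicate block is the unpaired fit, and a second fit with the replicate number as a block (residual df 2, prior df 3.02) is the paired fit. These fits, their thresholds, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for those said to be added later.

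The labels give the same biological replicate numbers in both groups and do not say what a number shares, so the pairing comes from the data. Over all probe sets, the deviations of same-numbered arrays from their group means correlated at 0.557, 0.896 and 0.837 for replicates 1, 2 and 3. All were above the minimum of 0.1 set for pairing, and each array correlated best with its own number. Untreated replicate 1 and treated replicate 3 also correlated, at 0.492, and untreated replicate 3 and treated replicate 1 at 0.373. The minimum therefore does not by itself tell matched from mismatched arrays, and the pairing of replicate 1 is the least certain. Blocked values are therefore printed beside results whose call they change.

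The named genes were chosen by a fixed rule: the 10 genes with the greatest rise and the 10 with the greatest fall among probe sets with 1 gene symbol that passed and whose treated and untreated ranges were apart, the 5 lncRNAs in each direction by the same criteria, up to 4 members with the smallest p of each gene list, and SERPINE1, SMAD7, CDH1, VIM, FN1, ESR1 and NKILA. Where fewer passed, the places were filled by the smallest unadjusted p. CALD1, NEDD9, LOXL4 and SMAD3, and further genes in the closing section, fall outside the rule and were chosen after their values were seen.

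The 22 gene lists were written from general knowledge: TGF-β pathway and direct targets, epithelial junction and identity, mesenchymal, EMT transcription factors, extracellular matrix and collagens, actin cytoskeleton and focal adhesion, estrogen receptor targets and luminal identity, G1/S and DNA replication, G2/M and mitosis, type I interferon response, NF-κB and inflammatory, p53 targets and apoptosis, hypoxia and glycolysis, unfolded protein and integrated stress response, cholesterol biosynthesis, known lncRNAs, snoRNA host lncRNAs, ribosomal proteins, basal and myoepithelial markers, fibroblast markers, endothelial and blood cell markers, and housekeeping. Of 679 listed genes 578 were analysed, and the others were not analysed here. DCN and LUM are in both the matrix and the fibroblast list. Each list was tested with camera at a preset correlation of 0.01 on 22271 genes, with Benjamini-Hochberg adjustment over the 22 lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. Members were also adjusted over the list alone.

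The fits were tested on simulated data with 65199 probe sets, 200 changed per run, in 10 runs. With independent arrays the unpaired fit recovered 2.54% of 1.5-fold, 46.7% of 2-fold and 85% of 4-fold changes with 5.51% false calls, and the paired fit 0%, 0% and 42.4% with 2.78% false calls. With arrays paired as in these data the unpaired fit recovered 0%, 24.3% and 75% with 0.152% false calls, and the paired fit 89.6%, 98.7% and 99.8% with 10.8% false calls (232 of 2152), above the nominal 5%. camera at the preset correlation called a shifted list and 0 of 20 unchanged lists in both fits. Those lists were random genes with independent noise. The real lists had estimated correlations of up to 0.828 (ribosomal proteins), with 0.107 for the TGF-β list and 0.048 for G2/M. The simulation therefore cannot show how often the preset correlation gives false calls for lists of correlated genes.

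The settings varied were quantile normalization and median centring of the arrays, filters at the median level and at the 25th percentile, trend and robust settings, array weights, the replicate block, leaving out each array in turn, a plain test without moderation, an adjusted p under 0.01, an unadjusted p under 0.05 with a 1.5-fold change, lncRNAs by symbol pattern, an estimated correlation, fry, and the mean of all probe sets of a gene. Further settings were added after seeing the data: leaving out both arrays of a replicate number, the block as a random effect, the block combined with quantile normalization, a filter or trend and robust settings, and gene-by-gene array weights. The median change of all probe sets was -0.02 as deposited, -0.008 after quantile normalization and -0.004 after centring. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.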

Results

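Expression was measured on 6 Affymetrix arrays of RNA from MCF7, an established human breast cancer cell line. In 3 arrays the cells had received 10 ng/ml of transforming growth factor β1 (TGF-β1), a secreted cytokine, over 4 days with a renewal every 2 days, and in 3 arrays the cells were untreated. Each array held a log2 signal for 65199 probe sets, with array medians between 5.42 and 5.51. The number of arrays limits the precision of every value. The stated purpose was to find long noncoding RNAs (lncRNAs) regulated by TGF-β, so treated and untreated arrays were compared, and every change is given as treated minus untreated on the log2 scale.

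A small set of transcripts rose strongly after TGF-β1. AMIGO2, which encodes a cell adhesion molecule, rose from 7.20 ± 0.05 to 9.05 ± 0.10 (mean ± SD, n = 3 and 3), a change of +1.85 (SE 0.083) or 3.62-fold, with a limma adjusted p of 0.0178. ADAM19, which encodes a membrane metalloprotease, rose from 8.25 ± 0.05 to 9.56 ± 0.04, a change of +1.31 (SE 0.071) or 2.48-fold, with an adjusted p of 0.0281. In both genes all 3 treated arrays lay above all 3 untreated arrays. In total 5 probe sets passed an adjusted p of 0.05, 5 higher and 0 lower, and all 5 changed by at least 2-fold. The remaining 3, named after their values were seen, hold no single gene: TC20001671.hg.1 rose by +3.15 (SE 0.14) and TC19002541.hg.1 by +2.66 (SE 0.15), neither being listed in the probe annotation, and 1 whose entry joins several genes rose by +2.39. At an unadjusted p under 0.05 the unpaired fit gave 1642 probe sets, where chance gives 3259.95 for independent arrays. A fit with the replicate number as a block gave 7476 probe sets at that level. Treated and untreated ranges were apart in 6.75% of probe sets. Chance gives 10% for 3 against 3 only where arrays are independent, and same-numbered arrays deviated together.

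Arrays of the same replicate number deviated together, and a limma fit with the replicate number as a block (the paired fit) called 101 probe sets, 90 higher and 11 lower, including the 5 above. Of these 101, 46 changed by at least 2-fold, 44 up and 2 down, and 58 carried the name of a single gene, of which 51 rose and 7 fell. Known components and targets of TGF-β signalling were among them. SKIL, which encodes a repressor of SMAD proteins, rose in the paired fit from 7.32 ± 0.09 to 8.77 ± 0.22 (+1.45, adjusted p 0.0261 paired, 0.0845 unpaired). SMAD7, which encodes an inhibitory SMAD, rose in the paired fit from 6.77 ± 0.04 to 8.10 ± 0.32 (+1.32, adjusted p 0.0499 paired, 0.212 unpaired), and PMEPA1, which encodes a further inhibitor of the pathway, by +1.68 (0.0327 paired, 0.106 unpaired). JUNB, which encodes an AP-1 transcription factor, rose in the paired fit by +1.03 (0.0327 paired, 0.0692 unpaired). In data simulated with paired arrays the paired fit made 10.8% false calls at the nominal 5% level, so its 101 calls are less certain than their adjusted p states. The unpaired count of 5 became 1 without untreated replicate 3 and 0 without any other single array, and the paired count of 101 became 14 without both replicate 2 arrays and 0 without both arrays of replicate 1 or of replicate 3.

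Further genes with the smallest p outside these signalling genes rose in the paired fit at adjusted p values of 0.0261 to 0.0327 and missed the threshold in the unpaired fit at 0.0692 to 0.0971. ODAPH, a gene of tooth enamel mineralisation, had the greatest change of these (4.88 ± 0.03 to 7.29 ± 0.41, +2.41). FERMT1, which encodes an activator of integrins, rose by +1.49, the zinc finger gene ZNF41 by +1.06 and KPNA7, which encodes a nuclear import receptor, by +1.05. LHB rose by +1.33, but it is a member of a family of near-identical hormone subunit genes, so the copy measured is uncertain. MYH16 rose by +1.31 on its brighter probe set and differed by -0.04 on its other probe set, so its probe sets disagree. In the falling direction no gene passed unpaired. PTX3, which encodes a secreted pentraxin, fell in the paired fit from 9.33 ± 0.08 to 8.31 ± 0.09 (-1.02, adjusted p 0.0456 paired, 0.0822 unpaired). SLC14A1, which encodes a urea transporter, fell in the paired fit by 0.83 (0.0366 paired, 0.0973 unpaired), ADGRF1, which encodes an adhesion receptor, by 0.81 (0.0352 paired, 0.142 unpaired) and ETV1, which encodes an ETS transcription factor, by 0.66 (0.0464 paired, 0.182 unpaired). A further 6 genes with the smallest p in that direction passed in neither fit, with changes of -1.02 for STC1, -0.83 for CRLF2, -0.77 for EVI2A, -0.68 for PEG10, -0.55 for ARSJ and -0.53 for PTGER4 and paired adjusted p values of 0.0515 to 0.101.

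**Figure D1:**
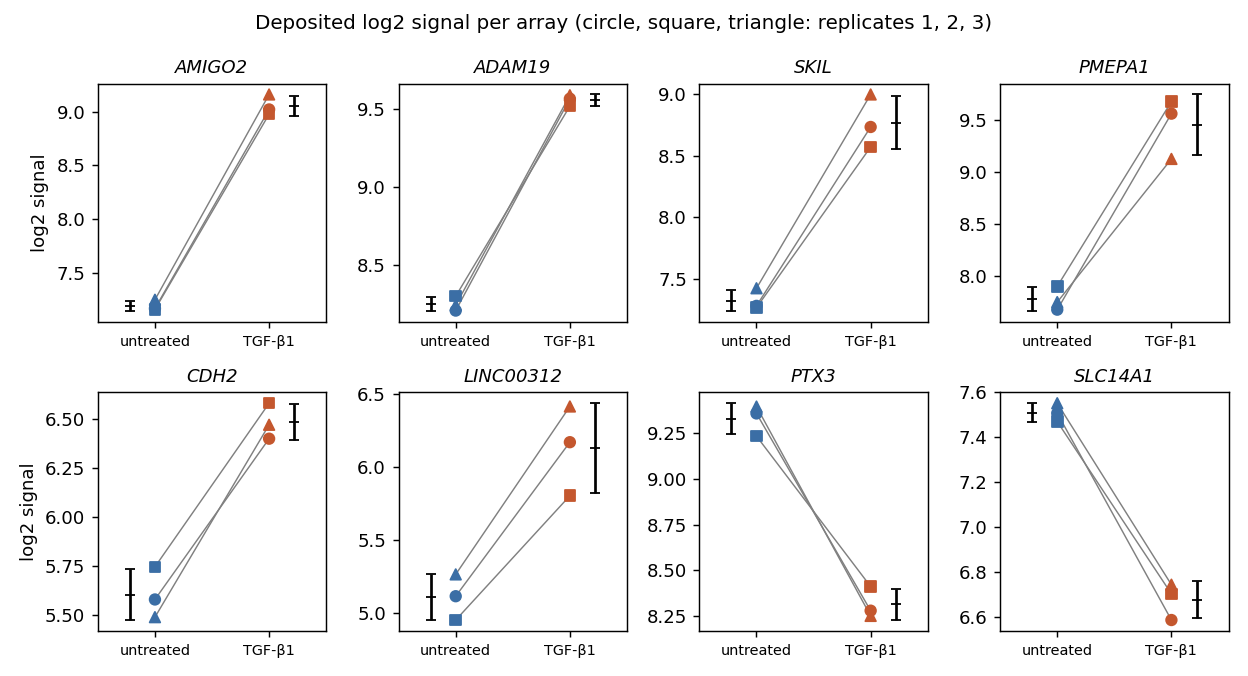
Deposited log2 signal (vertical axes, one scale per gene, not starting at 0) of 8 genes on each untreated (blue) and TGF-β1 (orange) array. Grey lines join arrays of the same replicate number and black bars show the mean ± SD of 3 arrays; AMIGO2 and ADAM19 passed in the unpaired fit and the others only in the paired fit, and in every panel the ranges of the groups are apart.

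Among probe sets named as lncRNAs none passed in the unpaired fit. The 41184 probe sets not listed in the annotation carry no gene type here, so any lncRNAs among them were not counted. They held 2 of the 5 unpaired calls and 35 of the 101 paired calls. Of the 1974 lncRNA probe sets limma called 0 unpaired, and a plain test without variance moderation also called 0. At an unadjusted p under 0.05 limma gave 46 unpaired and 166 paired, where chance gives 98.7. The paired fit called 3, all higher. LINC00312 rose in the paired fit from 5.11 ± 0.16 to 6.13 ± 0.31 (+1.02, adjusted p 0.0407 paired, 0.497 unpaired), LINC03033 from 7.17 ± 0.21 to 7.92 ± 0.15 (+0.75, 0.0467 paired, 0.605 unpaired), and MIR181A2HG, the host transcript of a microRNA pair and named after its values were seen, from 6.18 ± 0.49 to 7.14 ± 0.54 (+0.96, 0.0327 paired, 0.99997 unpaired). The treated and untreated ranges were apart for LINC00312 and LINC03033 but not for MIR181A2HG, which was higher in all 3 pairs. The other lncRNAs with the smallest p and a higher mean passed in neither fit: LINC02551 (+0.55), LINC00452 (+0.80 on one probe set and +0.11 on the other) and GAS6-DT (+0.35), with paired adjusted p values of 0.0622, 0.0619 and 0.188. Those with a lower mean passed in neither fit either, with differences of -0.62 for SOCS2-AS1, -0.49 for PGM5-AS1, -0.42 for SPATA13-AS1, -0.32 for FAM138C and -0.30 for FAM27E2 and paired adjusted p values of 0.0537 to 0.288. The lncRNA NKILA was not analysed here, and of 59 genes on the list of known lncRNAs 40 were measured. Without both replicate 2 arrays the paired fit called 0 lncRNA probe sets. Among 17298 protein-coding probe sets limma called 2 unpaired and 54 paired, of which 47 rose and 7 fell.

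The list of TGF-β pathway members and direct targets rose as a group. Of its 35 measured genes 28 had a higher mean and 7 a lower mean after TGF-β1, with a median change of +0.21, and camera, which compares a list with all other genes, gave an adjusted p of 8.07e-23 over the 22 lists. None passed over all probe sets in the unpaired fit, 14 rose and 1 fell (SMAD3, -0.53) adjusted over the list alone (18 and 3 in the paired fit), and 6 rose in the paired fit over all probe sets: JUNB, SKIL, PMEPA1, SMAD7, LMCD1 (+1.09, adjusted p 0.0327 paired, 0.182 unpaired) and NEDD9 (+0.76, 0.0456 paired, 0.243 unpaired). SERPINE1 was not analysed here.

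Mesenchymal genes, which are typical of motile connective tissue cells, also rose as a group, with 22 of 29 higher and 7 lower (median +0.16, camera adjusted p 1.35e-15). Adjusted over the list alone 8 rose and 0 fell (12 and 0 in the paired fit), and 3 rose in the paired fit over all probe sets: CDH2, the N-cadherin gene, from 5.60 ± 0.13 to 6.49 ± 0.09 (+0.88, adjusted p 0.0364 paired, 0.182 unpaired), PLAU, the urokinase gene, from 9.19 ± 0.12 to 10.05 ± 0.05 (+0.86, 0.0387 paired, 0.142 unpaired) and CALD1, the caldesmon gene, by +1.02 (0.0327 paired, 0.794 unpaired). ITGA5 (+0.60) and LOX (+0.44) did not pass over all probe sets. VIM, the vimentin gene, was at 11.71 ± 0.09 untreated and 11.78 ± 0.02 treated, and FN1, the fibronectin gene, differed by +0.28 (adjusted p 0.204 paired). Neither passed over all probe sets, but FN1 rose in the paired fit adjusted over the list alone. By mean level over the 6 arrays both stood at percentile 99.7 of protein-coding genes, which may limit how far a rise could be seen.

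Matrix and actin genes moved the same way. In the list of extracellular matrix and collagens 27 of 39 genes were higher and 12 lower (median +0.11, camera adjusted p 5.73e-11), with ADAM19 passing over all probe sets. Adjusted over the list alone 6 rose, including MMP10 (+0.60), COL1A1 (+0.47) and COL1A2 (+0.51), and 1 fell (LOXL4, -0.45), against 15 and 5 in the paired fit. In the list of actin cytoskeleton and focal adhesion 20 of 29 genes were higher and 9 lower (median +0.11, camera adjusted p 2.54e-07), and 4 rose adjusted over the list alone: FERMT2 (+0.41), PTK2 (+0.38), PDLIM7 (+0.35) and MYO10 (+0.77), against 7 in the paired fit. MYO10, which encodes an unconventional myosin, also rose in the paired fit over all probe sets (adjusted p 0.0460 paired, 0.99997 unpaired).

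Genes of G2/M and mitosis fell as a group, by small amounts. All 37 measured genes had a lower mean after TGF-β1, with a median change of -0.34 and a camera adjusted p of 3.84e-19. None passed over all probe sets in either fit. Adjusted over the list alone 1 fell unpaired (KIF20A, a mitotic kinesin gene, -0.60), and 35 fell in the paired fit. NDC80 (-0.45), BUB1 (-0.40) and NUSAP1 (-0.36), which act at kinetochores and the spindle, did not pass adjusted over the list alone without the block. In the list of G1/S and DNA replication 18 of 38 genes were higher and 20 lower, and camera gave no call (adjusted p 0.197); its median was -0.006 as deposited and turned positive under both other scalings. That list was called higher without both replicate 3 arrays in the paired fit (0.0450).

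These 5 lists, for TGF-β signalling, mesenchymal genes, matrix, actin and G2/M, kept their camera call with an estimated correlation between genes (adjusted p = 0.0288 for each), and in the paired fit they kept it with the preset correlation. In the paired fit with an estimated correlation no list passed. The camera adjusted p was 0.218 for the TGF-β list and the mesenchymal list, 0.221 for matrix, 0.291 for actin and 0.421 for G2/M. With an estimated correlation camera uses the residual df of the fit, 4 unpaired and 2 paired. The loss of calls in the paired fit may therefore come from the few df, and was not told apart from an effect of correlated genes.

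camera called a further 3 lists with the preset correlation and not with an estimated one. Type I interferon response genes fell as a group, with 24 of 31 lower and 7 higher (median -0.12, camera adjusted p 0.000344), but adjusted p = 0.401 with an estimated correlation; IFIT3 (-0.34) and IFIT2 (-0.47) had the smallest p and did not pass over all probe sets. Adjusted over that list alone limma called 0 unpaired, with 4 at an unadjusted p under 0.05, and IFIT3 fell in the paired fit. Hypoxia and glycolysis genes rose as a group, with 21 of 31 higher and 10 lower (median +0.13, camera adjusted p 2.13e-06), but adjusted p = 0.110 with an estimated correlation; PFKFB4 (+0.47) and VEGFA (+0.60) did not pass over all probe sets. Adjusted over that list alone limma called 0 unpaired, with 3 at an unadjusted p under 0.05, and 11 rose in the paired fit, PFKFB4 and VEGFA among them. EMT transcription factors, which drive epithelial cells towards a mesenchymal state, had 8 of 16 genes higher and 8 lower with a median of +0.001 and a mean of +0.08. Camera called that list higher at an adjusted p of 0.0333, with adjusted p = 0.688 with an estimated correlation and 0.0743 in the paired fit. SNAI1 (+0.74) and SOX4 (+0.31) were higher and ZEB1 (-0.16) lower, and none of them passed over all probe sets. Adjusted over that list alone limma called 0 unpaired, with 2 at an unadjusted p under 0.05, and 2 rose in the paired fit, SNAI1 and SOX4. Without 1 array the call of the EMT transcription factors was lost, at 0.0536 without untreated replicate 1, 0.121 without untreated replicate 3, 0.0718 without treated replicate 1 and 0.254 without treated replicate 2, and its median turned to -0.05 without untreated replicate 3 or treated replicate 2. The call was also lost with the filter at the median level (0.0909), with fry (0.861), without both replicate 2 arrays (0.194 unpaired, 0.186 paired) and without both replicate 1 arrays in the paired fit (0.171).

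**Figure D2:**
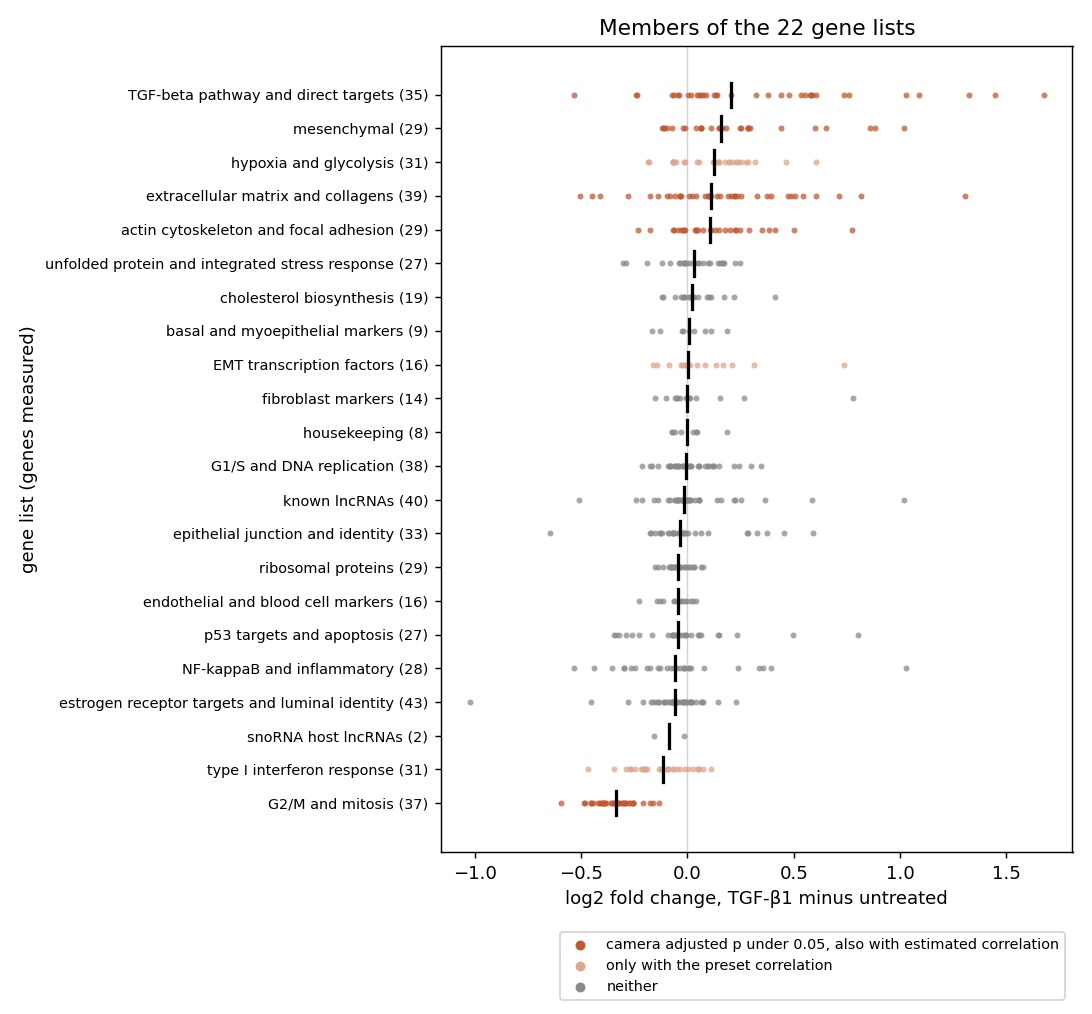
Log2 fold change, TGF-β1 minus untreated (horizontal axis), of each measured gene (points) in the 22 lists, with the number of genes in brackets and the list median as a black bar. All 37 genes of G2/M and mitosis lie below 0, and the TGF-β list has the highest median, +0.21; colours give the camera result of the unpaired fit, and the medians of the fibroblast, G1/S and housekeeping lists change sign with the scaling.

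The epithelial junction and identity list was not called (camera adjusted p 0.613), with 10 of 33 genes higher and 23 lower, a median of -0.03 and a mean of +0.007, and camera pointed to higher. CDH1, the E-cadherin gene, was at 5.94 ± 0.05 untreated and 6.26 ± 0.03 treated and did not pass over all probe sets (+0.33, adjusted p 0.873 unpaired, 0.151 paired), and neither did CLDN1 (-0.65), a claudin gene, or KRT8 (+0.45), a keratin gene. Single genes of the list moved in both directions in the paired fit: adjusted over the list alone 6 rose, including CDH1 and KRT8, and 1 fell (CLDN1), against 0 unpaired in limma, with 3 at an unadjusted p under 0.05. Estrogen receptor targets and luminal identity genes were not called either (camera adjusted p 0.0625, median -0.06, 32 of 43 lower), although they were called lower without untreated replicate 3 (adjusted p 0.0170), without treated replicate 2 (0.00456), without both replicate 2 arrays (0.0198 unpaired, 0.0326 paired) and with gene-by-gene array weights (0.0478). Adjusted over the list alone STC1 fell in the unpaired fit, and 2 fell in the paired fit, STC1 and IRS1 (-0.45). ESR1, the estrogen receptor gene, differed by -0.006 ± 0.088 (SE). By mean level over the 6 arrays, ESR1 stood at percentile 23.2 of protein-coding genes and CDH1 at 30.8. Levels this low may limit how far a fall could be seen, so these values do not show that TGF-β1 spared either gene. The NF-κB and inflammatory list was not called (camera adjusted p 0.167, median -0.06), but PTGS2, the cyclooxygenase gene, rose in the paired fit from 6.38 ± 0.39 to 7.41 ± 0.57 (+1.03, adjusted p 0.0460 paired, 0.99997 unpaired), and CSF1 (-0.53) fell adjusted over the list alone, where 3 rose and 7 fell in the paired fit. In the list of p53 targets and apoptosis (camera adjusted p 0.960, median -0.05) TP53I3 (+0.80) rose adjusted over the list alone, where 3 rose and 5 fell in the paired fit.

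No call was made for the unfolded protein and integrated stress response (camera adjusted p 0.138, median +0.03) or cholesterol biosynthesis (0.0584, median +0.02), although the former passed without treated replicate 3 (0.0367), without both replicate 3 arrays in the paired fit (0.00973) and with gene-by-gene array weights (0.0176), and the latter without untreated replicate 2 (0.0294), without both replicate 2 arrays (0.0298 unpaired, 0.0326 paired) and with gene-by-gene array weights (0.0176). STARD4 (+0.41), on the cholesterol list, rose adjusted over the list alone in the paired fit only. Known lncRNAs were not called (0.616); their median was -0.02, their mean +0.03 and the camera direction higher, and adjusted over the list alone LINC00312 rose in the unpaired fit, against 3 that rose and 1 that fell in the paired fit. Of the snoRNA host lncRNAs 2 were measured (0.561, median -0.09). Ribosomal protein genes were not called (0.915), with a median of -0.04 and a camera direction of higher; without untreated replicate 3 they were called lower (median -0.25, adjusted p 0.0369) and without treated replicate 3 higher (median +0.21, adjusted p 0.000807). Housekeeping genes were not called (0.553), and their median of -0.004, mean of +0.007 and camera direction of higher differed in sign.

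Markers of other cell types a culture could hold were not called. Basal and myoepithelial markers had a camera adjusted p of 0.455 (median +0.005, 9 genes) and endothelial and blood cell markers 0.384 (median -0.05, 16 genes). Fibroblast markers had 0.167 (median -0.004, mean +0.06, camera direction higher, 14 genes), with a median that turned positive under both other scalings. PDGFRB, a receptor gene on the fibroblast list, rose in the paired fit from 7.62 ± 0.08 to 8.39 ± 0.10 (+0.78, adjusted p 0.0352 paired, 0.182 unpaired).

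The replicate 2 arrays of both groups stood apart from the other arrays. The untreated and treated replicate 2 arrays correlated with each other at a Pearson r of 0.994 across probe sets and with the other 4 arrays at 0.946 to 0.976, and component 1 of a principal component analysis, with 79.6% of the variance, separated them. Ribosomal protein genes were higher on the replicate 2 arrays than on the others by a median of 0.59, against 0.15 for all protein-coding probe sets, while snoRNA probe sets were lower (median -0.83). The medians of this difference were 0.20 for the TGF-β list, 0.09 for the mesenchymal list, 0.05 for matrix, -0.06 for actin and 0.12 for G2/M. Genes are not independent replicates in these correlations.

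**Figure D3:**
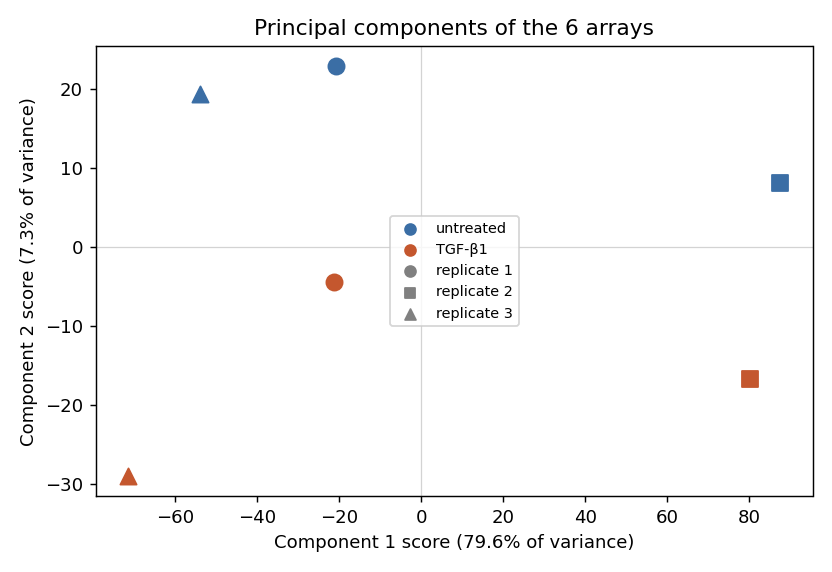
Scores of the 6 arrays on components 1 and 2 of a principal component analysis (79.6% and 7.3% of the variance, no unit), with untreated arrays in blue, TGF-β1 arrays in orange and the replicate number as the marker shape. Both replicate 2 arrays lie far from the other 4 along component 1.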

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

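The tests that take the block as a random effect, combine the replicate block with another setting, leave out both arrays of a replicate number, or use gene-by-gene weights were chosen after the result was seen; the others were planned. Counts are given in the order all probe sets, 2-fold, lncRNA and protein-coding, against 5, 5, 0 and 2 in the unpaired fit, and the lists against 8; a count not given was within 1.5 times of these. The replicate block gave 101, 46, 3 and 54 and ended the call of the EMT transcription factors; beyond these, the genes and list members given as passing in the paired fit and the list tests given with the block, it changed no other call. Leaving out 1 array gave 0 to 1, 0 to 1, 0 and 0 (lists 7 to 10). Each of these fits had fewer arrays and left 1 replicate number in 1 group only, and the effects of these were not told apart. Median centring and trend with robust settings each gave 4, 4, 0 and 1. The plain t-test gave 0, 0, 0 and 0, and an adjusted p under 0.01 gave 0, 0, 0 and 0, the latter by construction. An unadjusted p under 0.05 with a 1.5-fold change gave 256, 60, 9 and 118. Array weights gave 49110, 129, 1515 and 12230, but their estimation did not converge (weight 764.6 for treated replicate 1 and 0.0665 for untreated replicate 2), so these counts are not interpreted; ESR1 reversed there, at +0.045 (adjusted p 0.00449). Gene-by-gene weights gave 1397, 76, 30 and 500. For the lists, an estimated correlation and fry each gave 5; with the block the former gave 0 and fry 4, without actin and G2/M (adjusted p 0.0570 each) and with hypoxia and glycolysis (0.0181). The ribosomal list reversed without untreated replicate 3, at a median of -0.25, and leaving out 1 array gave medians from -0.26 to 0.21. For the settings in this paragraph with no cause given, the cause was not tested.

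With both replicate 2 arrays left out the counts were 0, 0, 0 and 0 unpaired and 14, 14, 0 and 2 with the replicate block; all 14 were among the 101, all 101 kept their sign, and 4 of the 5 probe sets called unpaired were among the 14. With the block and both arrays of replicate 1 or of replicate 3 left out, the counts were 0, 0, 0 and 0 each. The block as a random effect (consensus correlation 0.706) gave 305, 58, 6 and 179. The ordinary block gave, with trend and robust settings, 460, 60, 9 and 278, with quantile normalization 76, 37, 2 and 38, and with the filter at the median level 398, 59, 9 and 236. The causes were not tested.

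Quantile normalization, the filters and the mean of all probe sets moved no count by more than 1.5 times (the filter at the median level ended the call of the EMT transcription factors) and symbol patterns gave 0 lncRNA probe sets. AMIGO2 kept its call in 14 of 24 settings (log2 change 1.8011 to 1.8925, adjusted p 1.59e-08 to 0.407) and ADAM19 in 11 of 24 (1.2822 to 1.3575, adjusted p 1.71e-08 to 0.499), the lowest p being from the weights that did not converge. No setting was needed for a pseudocount, since the values were already log2. Signal over background was not used here, so limits on dim probe sets are unknown.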

Other observations

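Tests of short RNA loss (snoRNA, miRNA and protein-coding), and all tests of the luminal pattern, were chosen only after the result was seen; the genes in the next paragraphs were chosen after their values were seen.

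Other named genes passed only in the paired fit, whose false calls exceeded the nominal level in simulated data; they were picked from its calls and no theme was tested. PLEK2, a pleckstrin family gene, rose by 1.22 on the log2 scale in the paired fit, LBH, a transcription cofactor gene, by 1.17, CSRP2, which encodes a LIM domain protein, by 1.10 and PODXL, the podocalyxin gene, by 0.98. KRT7, a simple epithelial keratin gene, rose by 0.91 (adjusted p 0.0438 paired, 0.106 unpaired), EDN1, the endothelin gene, by 0.85, SEMA7A, a semaphorin gene, by 0.79 and IGFBP3, which encodes an insulin-like growth factor binding protein, by 0.67 (adjusted p 0.0499 paired, 0.570 unpaired). In the falling direction EVI2B was at -0.96, SOCS2, a suppressor of cytokine signalling gene, at -0.75 (adjusted p 0.0364 paired, 0.99997 unpaired) and EMP1, a membrane protein gene, at -0.64.

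Some lncRNAs lay next to a protein-coding gene that moved the same way. LINC00312 and its neighbour LMCD1 rose together in the paired fit (+1.02 and +1.09). SOCS2-AS1 was at -0.62 beside SOCS2 at -0.75, and APCDD1L-DT at +0.63 beside APCDD1L at +0.68, where the lncRNA of each pair missed the threshold (paired adjusted p 0.0537 and 0.0608). MIR181A2HG (+0.96) and its neighbour NR6A1 (-0.27) are a counterexample. Across 1897 pairs of an lncRNA and its nearest protein-coding gene, the changes correlated at a Spearman rho of 0.167 and a Pearson r of 0.245; the highest rho of 10000 shuffles was 0.0747, which gives a one-sided permutation p of 1e-04, the smallest they can give. Within each replicate pair rho was 0.126, 0.0686 and 0.125. The correlation is across genes, which are not independent replicates, so a change shared along the chromosome is a candidate explanation and stays a hypothesis.

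The splits of the arrays are too few to give a share under 0.05. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probe sets as the real one (5, highest other 0), 1 as many at 2-fold (5, highest other 0), 10 as many lncRNA probe sets (0, highest other 0) and 1 as many protein-coding ones (2, highest other 0), and the smallest share is 0.1. In the paired fit 4 splits part all 3 pairs; 1 gave as many as the real 101, the highest other was 13, and the smallest share is 0.25.

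The replicate 2 arrays of both groups stood apart, and technical and biological explanations were tested. A difference in signal scale left in the deposited values is argued against. After removal of its trend on level, 99.96% of the SD of the replicate 2 difference remained (0.4945 before, 0.4943 after). The deposited arrays already had similar upper quartiles (7.04 to 7.09), so this cannot decide about the signals before processing. Loss of short RNAs stays open for the snoRNA probe sets (median -0.8799, 240 genes, random range 0.1026 to 0.1522) and the miRNA probe sets (median 0.05564, 1039 genes, random range 0.1155 to 0.1365). Their values prompted that explanation and do not test it. A loss confined to short RNAs would leave protein-coding probe sets in place. Their replicate 2 deviations correlated between treated and untreated at 0.945, but a correlation gives no size. The median replicate 2 difference of protein-coding probe sets was 0.1452, with 1.289% lower and 0.7978% higher by at least 2-fold, against 47.74% of snoRNA probe sets lower. For most protein-coding probe sets the difference was thus small, and the correlation does not decide its source. Cells of another type stay open, since the fibroblast and the endothelial and blood lists, at percentiles 85.17 and 83.47, lay inside the range of random lists and hold mostly dim genes (median untreated levels 4.95 and 5.049), so the bound set beforehand, a percentile under the upper limit, could not exclude them. Different cycling stays open, because the G2/M members went both ways (replicate 2 difference from -1.51 to 1.07, SD 0.590), so that their median, at percentile 29.38, and that of the G1/S list, at 87.32, would lie inside the random range, as the bound set beforehand asks, even where single members moved strongly; also open is the source of the difference in ribosomal protein genes (+0.5896).

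The mesenchymal list had a median untreated level of 8.967, at percentile 100 of random lists of its size. The luminal list, at 6.628, lay inside the random range of 6.402 to 7.759 and was set apart neither as dim nor as bright. TGF-β1 is argued against as the source of these levels, since they were measured in untreated cells and the luminal list differed by a median of -0.05994 between groups. The luminal list stood at percentile 8.78 of protein-coding lists and 41.08 of named gene lists. Random lists do not give the level that the line named in the labels should have. For the luminal genes these percentiles therefore decide neither for nor against probe sets that report poorly or a culture that differs from that line. Single genes were ranked by mean level over the 6 arrays among protein-coding genes. Of luminal and epithelial genes, PGR stood at percentile 1.62, ESR1 at 23.2, CDH1 at 30.8, FOXA1 and GREB1 at 33.8 each and EPCAM at 43.6. TFF1 stood at 52.2 and GATA3 at 55.1, and the epithelial keratin genes KRT8 (98), KRT18 (97.4) and KRT19 (98.4) were high. Of mesenchymal genes, VIM, FN1 and AXL stood at 99.7 each and CD44 at 98.8, while CDH2 (29.9) and SPARC (44.7) were not high. The EMT transcription factors ZEB1 and SNAI2 stood at 87.2 and 84.8. Probe sets that report poorly would give low levels. The mesenchymal list, above the random range of 6.209 to 7.905, argues against them as the source of its own level. For the luminal list both explanations stay open, because levels of different probe sets depend on their probes. A culture that differs from the line named in the labels stays open for both lists.

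In the paired fit 3 of 1974 lncRNA probe sets and 54 of 17298 protein-coding ones passed, a difference that Fisher's exact test did not separate (two-sided p 0.276, odds ratio 0.486). A lower share of lncRNA probe sets was therefore not established. Random protein-coding sets matched on level held a mean of 2.354 calls, with nearly all of them between 0 and 6. No count can fall under that range, so it cannot decide whether a lower signal of lncRNA probe sets plays a part.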
